A study of Oryza sativa with 12 samples.

How the data were processed

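Leaves of the rice varieties QJ10 and LJ31 (QJ and LJ in the column headers and here), as controls or under bicarbonate salt-alkali stress at 200 mmol/L, were sequenced from total RNA on the NovaSeq X Plus platform per the labels. There were 4 groups of 3 libraries. Samples were assigned to groups by the sample titles, and each per-sample column was matched to a title by group and replicate number. The library names in the sample descriptions were not used for this, since the 3 QJ control samples share 1 name, that of replicate 1, and so do the 3 stressed QJ samples. For QJ the match to single replicates therefore rests on titles alone, while group membership does not depend on it. The deposited values are FPKM (fragments scaled to transcript length and library size) per gene and library, with group means, log2 fold changes and p-values with adjusted p-values computed by the authors. The aligner, the genome build, the counting of reads shared by near-identical gene copies and the authors' test are not given in the sources used here. Values of gene families with close copies, such as laccases, peroxidases and lipid transfer proteins, carry that uncertainty.

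Each of the 4 deposited tables lists only genes with an adjusted p under 0.05 and a log2 fold change of at least 1 in size in the authors' test, as tested on the values. The 2 stress tables carry the name of the other variety than their columns do. The column headers were used. Each library had the same value wherever it appeared, with 0 of 31572 values present in more than 1 table differing. The headers thus match each other across tables. They would also match with the 2 varieties exchanged in every header, so that match cannot decide between headers and table names. The variety labels here rest on the headers alone. The tables held 13674 genes, 5422 of them with a name and 38 with a description, and 5534 had values in all 12 libraries. FPKM ratios differed from the authors' log2 fold changes by a median shift of 0.145 in QJ stress, -0.142 in LJ stress, 0.150 between controls and 0.354 between stressed groups. No rescaling was applied to the main values.

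Limma (version 3.58.1 in R 4.3.3) was fitted with a trended prior to log2(FPKM + 1), per table, for genes with at least 1 FPKM in at least 3 libraries. The difference of the stress responses was fitted over all 12 libraries on the genes with values in every library. Tests were two-sided, adjusted by Benjamini-Hochberg, and passed at an adjusted p under 0.05. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9. Replicate numbers were not used as pairs in any comparison, since values with the same number were not more alike across groups.

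The comparisons, tests, 39 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Lists were to be matched by symbol or description. As few genes had a description, stems of gene names were added after the data were seen, from names alone, and gave 982 of 1307 list memberships. The list of chloroplast ribosomal proteins matched no gene. Lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The rule named, per comparison, the 5 genes with the largest rise and the 5 with the largest fall among passing named genes with separate groups and a mean of at least 5 FPKM in the higher group. It added up to 3 members of each of the 8 lists with the largest share passing and, for stress, a fixed set of salt-stress genes. For the difference of responses the rule could be read as the 5 largest each way or the 10 largest in size. This was settled after values were seen by naming the genes of both readings, which added OsOxO3. Ties between lists were broken by the number passing, also chosen afterwards. In each comparison of a pair of groups all 8 lists taken had 100% of tested members passing. The choice there favoured large lists and does not rank families by response.

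The alternatives tried were other pseudocounts, other filters, a threshold of 1 on the log2 scale, median centring, quantile normalization, the scaling of the authors' fold changes, limma without trend or with a robust prior, a replicate block, a joint fit, and leaving out each library in turn. Other splits of the libraries were fitted, 10 for each pair of groups and 100 drawn with a fixed seed for the difference of responses. The procedure was tested on simulated data with known changes. Of genes changed by 1 on the log2 scale it recovered 97.0% to 100%, and of those changed by 0.5 it recovered 83.6% to 88.1% in the pair comparisons and 43.3% for the difference of responses. Between 1.46% and 5.48% of its calls were false. A planted list was called in each of the 5 comparisons and 0 of 20 unchanged lists in any. The simulated genes varied independently, few of them changed and none were selected for a change. The real tables differ in this, so these rates need not hold for them.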

Results

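Gene expression was measured by RNA sequencing in leaves of 2 rice varieties, QJ10 and LJ31, written QJ and LJ here as in the column headers of the tables, grown as controls or under bicarbonate salt-alkali stress at 200 mmol/L. Each of the 4 groups had 3 libraries, which the series record calls biological replicates, 12 libraries in all. The deposited tables list, for each of 4 pairs of groups, only the genes the authors had already selected as changed, 13674 genes over all 4 tables. Reads per library are not given in the sources used here, so the depth is unknown and no counting interval could be computed. Listed FPKM values over the union of tables summed to 310974 to 312214 in the QJ controls, 302273 to 304097 in the stressed QJ libraries, 375808 to 376025 in the LJ controls and 521586 to 522465 in the stressed LJ libraries. These sums cover part of each library and are not its depth.

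Replicates lay close together. The median coefficient of variation between the 3 libraries of a group was 16.5% to 17.6% for genes at 1 to 3 FPKM and 1.53% to 2.08% for genes at 300 FPKM or more, over the 4 groups. Gene values are given as mean FPKM ± SD (n = 3 libraries per group), and fold changes come from a limma fit on the log2(FPKM + 1) scale, on which 1 was added to every value. Folds are given only for genes whose lower group had at least 1 FPKM. The added 1 still makes these folds smaller than ratios of group means where the lower group is low. Over the named genes the ratio was more than 1.5 times the fold in 10 of 81 gene results, all with a lower group of at most 1.71 FPKM, and up to 1.89 times. In LJ stress it was 493 for OsLEA3-1 and 179 for Cht2*, against folds of 298 and 101, and in QJ stress 15.9 for OsLAC29, against 8.99. The p-values measure only the spread between these samples. With a spread this small, whether it includes the variation between plants cannot be told from these values. Because each table holds genes selected by the authors on the same libraries, nearly all tested genes passed, so the counts of passing genes and list members are not independent evidence of a response. A camera test compares a list with the other listed genes of its table only. Counts adjusted over the list alone equalled those over all genes tested for every list in the 4 pair comparisons.

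The first comparison asked which leaf genes changed in QJ under stress. Rab16A (Os11g0454300), a dehydrin that responds to abscisic acid, rose from 9.79 ± 1.13 to 631 ± 28.3 FPKM, 58.8-fold (5.88 on the log2 scale, SE 0.0767). The abscisic acid synthesis gene OSNCED3 (Os07g0154100) rose from 2.5 ± 0.194 to 53.1 ± 2.41 FPKM, 15.5-fold, and SGR (Os09g0532000), which acts in chlorophyll breakdown, from 32.3 ± 1.15 to 151 ± 2.17 FPKM, 4.55-fold. Of 17 tested genes of light harvesting and the photosystems, 16 fell, 0 rose and 1 did not pass (camera adjusted p = 6.60e-05, adjusted p = 0.20 with an estimated correlation). Among ethylene-response factors, ERF102 (Os09g0457900) fell from 681 ± 9.31 to 21.1 ± 1.45 FPKM, 30.8-fold (-4.95 on the log2 scale, SE 0.0491).

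Further genes with the largest rises were OsADF3 (Os03g0820500), an actin-depolymerizing factor, from 3.94 ± 1.17 to 304 ± 16.3 FPKM, 62.9-fold, and YSL2 (Os02g0649900), a metal-nicotianamine transporter, from 4.37 ± 0.373 to 183 ± 7.33 FPKM, 34.3-fold. Rir1b (Os10g0569800) went from 0.31 ± 0.139 to 96.4 ± 9.03 FPKM and OsMIR (Os12g0282000), a mitochondrial iron-regulated gene, from 0.157 ± 0.0802 to 48.7 ± 1.75 FPKM. The largest falls included qCTR12 (Os12g0550600), at 67.3 ± 1.6 FPKM in the controls and listed at 0 under stress, and OsTPP1 (Os02g0661100), a trehalose-6-phosphate phosphatase, from 253 ± 2.14 to 10.9 ± 1.08 FPKM, 21.4-fold. NHX1 (Os07g0666900), a vacuolar sodium/proton antiporter, rose from 4.66 ± 0.286 to 16.1 ± 1.34 FPKM, 3.02-fold.

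Transcription factor families moved in both directions. Of 39 AP2/ERF and DREB factors, 13 rose and 26 fell (camera adjusted p = 0.0633), among them OsERF#133 (Os09g0522100) from 64.1 ± 2.6 to 0.187 ± 0.162 FPKM and DERF3 (Os08g0474000) from 182 ± 6.33 to 7.61 ± 1.11 FPKM, 21.4-fold. WRKY factors had 13 rises and 19 falls in 32 (camera adjusted p = 0.157). OsWRKY104 (Os11g0117400) rose from 5.21 ± 1.12 to 53.6 ± 2.06 FPKM, 8.88-fold, whereas OsWRKY24 (Os01g0826400) fell from 520.4 ± 6.78 to 61.4 ± 1.8 FPKM, 8.35-fold, and OsWRKY61 (Os11g0685700) from 10.55 ± 1.34 to 0.103 ± 0.0896 FPKM. Of 28 NAC factors 15 rose and 13 fell (camera adjusted p = 0.875). The stress-responsive SNAC1 (Os03g0815100) fell from 1702 ± 29.7 to 356 ± 2.95 FPKM, 4.77-fold. OsNAC3 (Os07g0225300) fell from 180.4 ± 2.23 to 35.3 ± 0.577 FPKM, 5.0-fold, and ONAC012 (Os05g0442700) from 78.9 ± 1.87 to 12.5 ± 1.28 FPKM, 5.92-fold. Auxin genes had 5 rises and 16 falls in 21 (camera adjusted p = 0.0633). The auxin-responsive genes named all fell, OsSAUR2 (Os01g0768333) from 663 ± 36.1 to 106 ± 13.5 FPKM, OsSAUR15 (Os03g0660300) from 79.7 ± 4.35 to 5.93 ± 0.712 FPKM and OsSAUR16 (Os03g0660400) from 69.2 ± 5.14 to 6.06 ± 1.36 FPKM.

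Of 24 pathogenesis-related genes, 22 rose and 2 fell (camera adjusted p = 0.000623, adjusted p = 0.151 with an estimated correlation). The chitinases Cht3* (Os06g0726100) and Cht1*(Chi1) (Os06g0726200) rose from 5.82 ± 0.399 to 83.1 ± 3.9 FPKM, 12.3-fold, and from 37.3 ± 2.08 to 217 ± 9.13 FPKM, 5.68-fold, and the glucanase Gns2 (Os01g0944900) rose from 1.46 ± 0.605 to 26 ± 2.32 FPKM, 11.2-fold. Class III peroxidases had 6 rises and 18 falls in 24 (camera adjusted p = 0.0815). The gene prx136 (Os12g0111800) rose from 1.5 ± 0.55 to 31.4 ± 0.506 FPKM, 13.2-fold, and prx131 (Os11g0112200) from 4.24 ± 0.307 to 46.7 ± 2.49 FPKM, 9.1-fold, while prx29 (Os02g0240300) fell from 263 ± 8.55 to 48.1 ± 2.64 FPKM, 5.38-fold. In phenylpropanoid, lignin and flavonoid synthesis 18 of 24 rose and 6 fell (camera adjusted p = 0.0488, adjusted p = 0.20 with an estimated correlation). This call was lost without the genes of the 2 marker lists (camera adjusted p = 0.0549). The named members were laccases, of which OsLAC29 (Os12g0258700) rose from 1.15 ± 0.131 to 18.4 ± 1.24 FPKM, 8.99-fold, OsLAC28 (Os12g0257600) went from 0.317 ± 0.0503 to 7.49 ± 0.229 FPKM and OsLAC8 (Os01g0850700) fell from 55.6 ± 0.227 to 6.16 ± 0.317 FPKM, 7.91-fold. Among 23 genes of cell wall expansion and cellulose, 7 rose and 16 fell (camera adjusted p = 0.157). The expansin-like EXLB1 (Os07g0496250) rose from 0.497 ± 0.212 to 29 ± 0.911 FPKM. The xyloglucan endotransglucosylase/hydrolases OsXTH15 (Os06g0335900) and OsXTH11 (Os06g0696400) fell from 33.2 ± 1.6 to 3.89 ± 3.23 and from 29.5 ± 2.33 to 5.89 ± 1.2 FPKM.

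Other lists that passed in QJ were LEA proteins and dehydrins, with 20 rises and 1 fall in 21 (camera adjusted p = 0.000445, adjusted p = 0.151 with an estimated correlation). Diterpenoid phytoalexin genes had 19 rises and 2 falls in 21 (camera adjusted p = 0.00193, adjusted p = 0.151 with an estimated correlation). Abscisic acid genes had 15 rises and 1 fall in 16 (camera adjusted p = 0.00347, adjusted p = 0.151 with an estimated correlation). Phosphate starvation genes had 18 rises and 3 falls in 21 (camera adjusted p = 0.014, adjusted p = 0.183 with an estimated correlation). Iron genes had 8 rises and 1 fall in 9 (camera adjusted p = 0.0182, adjusted p = 0.22 with an estimated correlation). All 11 secondary wall markers tested fell (camera adjusted p = 0.014, adjusted p = 0.20 with an estimated correlation). Of the 33 members of that list in any comparison, 27 entered by a stem of the gene name, most of them fasciclin-like arabinogalactan genes. In limma with Benjamini-Hochberg adjustment, 3629 of 3641 tested genes passed, 1846 higher and 1783 lower under stress, and the adjusted p of the 34 genes named by rule was at most 0.000141. The groups did not overlap in any of the 34, which the naming rule required of the genes with the largest changes. None of the 9 list calls held with an estimated correlation.

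The second comparison asked the same of LJ. OsRMC (Os04g0659300), a cysteine-rich receptor-like protein, rose from 14.5 ± 2.03 to 5058 ± 92.2 FPKM, 329-fold (8.36 on the log2 scale, SE 0.0851). OsLEA3-1 (Os05g0542500), a late embryogenesis abundant protein, rose from 1.51 ± 0.258 to 746 ± 23.1 FPKM, 298-fold (8.22 on the log2 scale, SE 0.073). Rab16A rose from 6.3 ± 0.158 to 524 ± 9.44 FPKM, 71.9-fold, and OSNCED3 from 10.9 ± 0.68 to 178 ± 3.58 FPKM, 15.1-fold. All 27 light harvesting and photosystem genes fell (camera adjusted p = 7.15e-09, adjusted p = 0.071 with an estimated correlation), with the chlorophyll a/b-binding gene CAB1R (Os09g0346500) going from 672 ± 16 to 78.1 ± 1.29 FPKM, 8.51-fold lower. All 12 tested markers of shoot meristem and inflorescence fell as well (camera adjusted p = 0.000557, adjusted p = 0.0813 with an estimated correlation). OsMADS7 (Os08g0531700), a floral organ identity gene, went from 38.5 ± 1.69 FPKM in the LJ controls to 0.967 ± 0.351 FPKM.

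Other large rises were in OsEnS-107 (Os07g0529000), from 0.807 ± 0.0666 to 564 ± 7.8 FPKM, OsADF3, from 0.883 ± 1.04 to 413 ± 16.6 FPKM, and CYP76M2 (Os08g0508000), a cytochrome P450, from 0.503 ± 0.123 to 281 ± 2.73 FPKM. The largest falls were in OsChia1 (Os05g0399700), named as a chitinase, from 470.4 ± 10.8 to 0.10 ± 0.0693 FPKM. The lipid transfer protein genes OSC6 (Os11g0582500) and OsLTPd11 (Os10g0148000) fell from 154 ± 3.35 to 0.597 ± 0.254 FPKM and from 158 ± 6.64 to 1.4 ± 0.287 FPKM, 66.3-fold. OsLTP1.3 (Os03g0808500) was at 146 ± 10.4 FPKM and the tapetum gene RTS (Os01g0929600) at 122 ± 6.54 FPKM in the controls, and both were listed at 0 under stress. OSC6 and RTS are known from anthers. SGR rose from 39.2 ± 0.758 to 400.5 ± 11 FPKM, 9.98-fold, and NHX1 from 5.38 ± 0.265 to 37.5 ± 1.22 FPKM, 6.03-fold, whereas SKC1 (Os01g0307500), a sodium transporter, went from 2.04 ± 0.145 to 0.23 ± 0.121 FPKM.

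Of 46 genes of cell wall expansion and cellulose, 5 rose and 41 fell (camera adjusted p = 7.33e-05, adjusted p = 0.0813 with an estimated correlation). The secondary wall cellulose synthases OsCesA4 (Os01g0750300) and CESA7 (Os10g0467800) fell from 97.4 ± 5.39 to 5.77 ± 0.845 FPKM, 14.6-fold, and from 28.4 ± 0.965 to 1.93 ± 0.225 FPKM, 10.1-fold, and the beta-expansin OsEXPB9 (Os10g0548600) from 9.47 ± 0.938 to 0.0467 ± 0.0404 FPKM. All 26 secondary wall markers fell (camera adjusted p = 5.99e-06, adjusted p = 0.0813 with an estimated correlation), in the same libraries in which the inflorescence markers fell. Of 41 class III peroxidases, 11 rose and 30 fell (camera adjusted p = 0.0149, adjusted p = 0.103 with an estimated correlation). The gene prx71 (Os05g0135500) fell from 90.2 ± 1.26 to 2.27 ± 0.347 FPKM, 28-fold, prx29 from 51.8 ± 4.81 to 0.77 ± 0.070 FPKM and prx39 (Os03g0234900) from 52.8 ± 0.828 to 0.723 ± 0.239 FPKM. The light harvesting genes Lhcb1.1 (Os01g0720500) and LHCB (Os03g0592500) fell from 307 ± 9.27 to 22.4 ± 2.56 FPKM, 13.3-fold, and from 651 ± 11.3 to 65.6 ± 0.122 FPKM, 9.78-fold. Phenylpropanoid, lignin and flavonoid genes had 16 rises and 11 falls in 27 (camera adjusted p = 0.32). OsLAC29 rose from 2.18 ± 0.0451 to 467 ± 3.61 FPKM, 147-fold, and OsLAC28 from 0.20 ± 0.080 to 99.5 ± 1.61 FPKM. The laccase Lac (Os03g0273200) fell from 23.6 ± 0.696 to 0.31 ± 0.052 FPKM.

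Pathogenesis-related genes had 33 rises and 6 falls in 39 (camera adjusted p = 0.000112, adjusted p = 0.0813 with an estimated correlation). The chitinase Cht2* (Os05g0399300) rose from 1.26 ± 0.126 to 227 ± 2.55 FPKM, 101-fold, and OsPR5 (Os03g0661600) from 2.08 ± 0.342 to 289 ± 2.07 FPKM, 94.6-fold. AP2/ERF and DREB factors had 16 rises and 19 falls in 35 (camera adjusted p = 0.683). OsERF#052 (Os05g0572000) rose from 6.13 ± 0.556 to 46.1 ± 3.29 FPKM, 6.6-fold, and DERF8 (Os12g0168100) from 6.33 ± 1.01 to 30.9 ± 2.25 FPKM, 4.37-fold, and OsERF#027 (Os01g0968800) fell from 25.2 ± 1.02 to 4.05 ± 1.19 FPKM, 5.28-fold. Glutathione S-transferases had 11 rises and 19 falls in 30 (camera adjusted p = 0.254). OsGSTU17 (Os09g0467200) rose from 94.2 ± 3.23 to 624 ± 13.3 FPKM, 6.57-fold, and OsGSTF11 (Os01g0353400) from 0.10 ± 0.173 to 21.9 ± 2.39 FPKM, whereas OsGSTF16 (Os03g0135200) fell from 7.9 ± 1.68 to 0.633 ± 0.32 FPKM. Of 29 phosphate starvation genes 18 rose and 11 fell (camera adjusted p = 0.219). The phosphate transporter OsSPX-MFS1 (Os04g0573000) rose from 2.47 ± 0.126 to 45.1 ± 1.83 FPKM, 13.3-fold, and the purple acid phosphatases OsPAP21b (Os11g0151700) and OsPAP9b (Os01g0800500) went from 2.09 ± 0.415 to 26 ± 2.45 and from 0.68 ± 0.139 to 15.4 ± 0.618 FPKM.

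Rising lists that also passed in LJ were LEA proteins and dehydrins, 17 of 17 (camera adjusted p = 0.000451, adjusted p = 0.103 with an estimated correlation). NAC factors rose in 22 of 25 and fell in 3 (camera adjusted p = 0.000996, adjusted p = 0.0813 with an estimated correlation). WRKY factors rose in 21 of 25 and fell in 4 (camera adjusted p = 0.00263, adjusted p = 0.0813 with an estimated correlation). Diterpenoid phytoalexin genes rose in 18 of 19 and fell in 1 (camera adjusted p = 0.00191, adjusted p = 0.0813 with an estimated correlation). Iron genes rose in 12 of 13 and fell in 1 (camera adjusted p = 0.00191, adjusted p = 0.0813 with an estimated correlation). Chlorophyll breakdown and senescence genes had 14 rises and 2 falls in 16 (camera adjusted p = 0.00564, adjusted p = 0.144 with an estimated correlation). Abscisic acid genes had 8 rises and 1 fall in 9 (camera adjusted p = 0.0176, adjusted p = 0.128 with an estimated correlation). Sodium, potassium and proton transport genes had 20 rises and 5 falls in 25 (camera adjusted p = 0.0177, adjusted p = 0.12 with an estimated correlation). The 5 cytosolic ribosomal protein genes fell (camera adjusted p = 0.0176, adjusted p = 0.128 with an estimated correlation). Of 6 Calvin cycle genes 5 fell and 1 rose (camera adjusted p = 0.0334, adjusted p = 0.228 with an estimated correlation). In limma with Benjamini-Hochberg adjustment 5970 of 5990 tested genes passed, 2974 higher and 2996 lower under stress. The adjusted p of the 38 genes named by rule was at most 4.30e-06. None of the 16 list calls held with an estimated correlation.

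The third comparison set the control leaves of QJ against those of LJ. Some genes known from anthers and floral organs were well above QJ in the LJ controls. OSC6 was at 154 ± 3.35 FPKM in LJ against 0.0367 ± 0.0635 FPKM in QJ, and OsMADS7 at 38.5 ± 1.69 FPKM in LJ and listed at 0 in QJ. All 15 tested markers of shoot meristem and inflorescence were lower in QJ (camera adjusted p = 0.012, adjusted p = 0.382 with an estimated correlation), as were all 30 secondary wall markers (camera adjusted p = 0.00173, adjusted p = 0.333 with an estimated correlation). OsCesA4 was at 97.4 ± 5.39 FPKM in LJ against 4.8 ± 0.172 FPKM in QJ, 17-fold (-4.09 on the log2 scale, SE 0.0573). All 5 circadian clock genes were higher in QJ (camera adjusted p = 0.00574, adjusted p = 0.382 with an estimated correlation).

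Further values between varieties are given for QJ against LJ. The genes most above LJ in QJ were qCTR12, at 67.3 ± 1.6 against 0.010 ± 0.0173 FPKM, and Sc-j (Os03g0247300), named for hybrid male sterility, at 33.8 ± 1.45 against 0.0633 ± 0.0709 FPKM. FAAH (Os04g0102700), a fatty acid amide hydrolase, was at 25.2 ± 0.139 against 0.123 ± 0.0306 FPKM. The wall-associated kinase OsWAK123 (Os11g0694100) and P0005H10.10-1 (Os01g0847100) were at 35.7 ± 1.31 and 19.2 ± 2.07 FPKM in QJ and both were listed at 0 in LJ. Those most below were OsChia1, at 0.040 ± 0.0693 against 470.4 ± 10.8 FPKM, and lipid transfer protein genes. OsLTP1.9 (Os11g0115100) was at 0.513 ± 0.0839 against 239.8 ± 7.36, OsLTP1.3 at 0.0567 ± 0.0981 against 146 ± 10.4 and OsLTPd11 at 0.22 ± 0.191 against 158 ± 6.64 FPKM.

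Cell wall expansion and cellulose genes were higher in QJ in 8 and lower in 51 of 59 (camera adjusted p = 0.0435, adjusted p = 0.382 with an estimated correlation), in the comparison in which the floral markers also differed. This call was lost with the scaling of the authors' fold changes (camera adjusted p = 0.0529) and without the genes of the 2 marker lists (camera adjusted p = 0.0852). The expansin OsEXPA7 (Os03g0822000) was at 0.29 ± 0.040 against 30.2 ± 0.918 FPKM and OsXTH3 (Os04g0631200) at 0.0667 ± 0.0651 against 13.3 ± 0.446 FPKM. The fasciclin-like arabinogalactan genes OsFLA9 (Os05g0163300), OsFLA8 (Os01g0159200) and OsFLA7 (Os01g0668100) were at 0.577 ± 0.309 against 67.4 ± 1.59, 1.06 ± 0.449 against 87.2 ± 1.25 and 0.343 ± 0.276 against 39.97 ± 1.03 FPKM. They entered the secondary wall list by family name, and not every family member is known from secondary walls. Class III peroxidases were higher in 19 and lower in 31 of 50, with a median of -1.06 and a test in the upward direction relative to the other listed genes (camera adjusted p = 0.55). The peroxidases prx39, prx41 (Os03g0339300) and prx130 (Os11g0112400) were at 0.0433 ± 0.0379 against 52.8 ± 0.828, 0.12 ± 0.060 against 12.8 ± 0.361 and 0.69 ± 0.171 against 19.5 ± 1.38 FPKM. Phenylpropanoid, lignin and flavonoid genes were higher in 6 and lower in 27 of 33 (camera adjusted p = 0.18). Their named members were Lac, at 0.0433 ± 0.0231 against 23.6 ± 0.696 FPKM, and the cinnamate 4-hydroxylases OsC4H (Os02g0467000), at 0.52 ± 0.171 against 21.8 ± 4.47, and C4H1 (Os02g0467600), at 4.92 ± 0.0854 against 69.7 ± 3.8 FPKM.

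AP2/ERF and DREB factors were higher in 10 and lower in 30 of 40 (camera adjusted p = 0.577). OsERF#027 was at 2.17 ± 0.206 against 25.2 ± 1.02, OsERF#061 (Os05g0361700) at 7.2 ± 0.554 against 59.8 ± 3.28 and OsERF#033 (Os04g0549700) at 0.28 ± 0 against 7.15 ± 0.395 FPKM. Of 36 auxin genes 8 were higher and 28 lower (camera adjusted p = 0.585). The auxin-responsive gene SAUR39 (Os09g0545300) was higher in QJ, at 44.3 ± 4.07 against 3.41 ± 0.796 FPKM, and OsIAA14 (Os03g0797800) and OsSAUR33 (Os08g0452500) were lower, at 0.637 ± 0.183 against 10.7 ± 1.09 and 0.94 ± 0.167 against 10.9 ± 1.35 FPKM. Heat shock factors and proteins were higher in 8 and lower in 25 of 33 (camera adjusted p = 0.602). Oshsp16.9B (Os01g0136200) was at 1.03 ± 0.123 against 22.5 ± 0.92, OsDjB2 (Os01g0875700) at 4.86 ± 0.581 against 29.5 ± 1.43 and OsHSP18.0-CIII (Os02g0782500) at 0.747 ± 0.563 against 6.65 ± 0.992 FPKM. Jasmonate genes were higher in 4 and lower in 24 of 28 (camera adjusted p = 0.0594). The named members were JMT-2 (Os02g0719600) at 20.7 ± 1.0 against 211 ± 1.49, the oxophytodienoate reductase OsOPR6 (Os06g0215500) at 3.66 ± 0.189 against 40.3 ± 2.92 and OsJAZ (Os07g0153000) at 0.32 ± 0.346 against 7.21 ± 1.51 FPKM. Limma with Benjamini-Hochberg adjustment passed 6088 of 6108 tested genes, 1897 higher and 4191 lower in QJ. Without LJ control replicate 1, 2 or 3 the lower genes were 2728, 2723 and 2725, since fewer genes then passed the filter, and 41.0% of passing genes were higher in QJ in place of 31.2%. The adjusted p of the 34 genes named by rule was at most 2.92e-05. None of the 4 list calls held with an estimated correlation, and without the genes of the 2 marker lists 1 list passed.

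The fourth comparison set stressed leaves of QJ against stressed leaves of LJ. WRKY factors were lower in QJ in 40 of 41 and higher in 1 (camera adjusted p = 0.000324, adjusted p = 0.383 with an estimated correlation). OsWRKY23 (Os01g0734000) was at 4.02 ± 0.874 against 101 ± 1.96 FPKM, 20.5-fold lower (-4.36 on the log2 scale, SE 0.12), and OsWRKY70 (Os05g0474800) at 23.3 ± 0.552 against 322 ± 7.51 FPKM, 13.3-fold. Light harvesting and photosystem genes were higher in QJ in 6 of 7 and lower in 1 (camera adjusted p = 0.0161, adjusted p = 0.383 with an estimated correlation). The pathogenesis-related gene OsPR1b (Os01g0382000) was at 88.5 ± 3.05 against 1.71 ± 0.30 FPKM, 33.2-fold higher in QJ, whereas Cht2* was at 14.2 ± 1.16 against 227 ± 2.55 FPKM, 15-fold lower.

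OsWAK123 was at 47.2 ± 1.91 against 0.0133 ± 0.0231 FPKM, and Sc-j and FAAH, at 40.3 ± 0.558 and 27.7 ± 1.39 FPKM in QJ, were both listed at 0 in LJ. The genes furthest below LJ were OsLTP1.9, at 0.107 ± 0.0924 against 103 ± 9.32 FPKM, the oxalate oxidase OsOxO3 (Os03g0693900), at 3.79 ± 0.469 against 414 ± 5.74 FPKM, 87-fold, and Sci1 (Os12g0437800), at 65 ± 5.51 against 1815 ± 16.7 FPKM, 27.6-fold. The metallothionein OsMT1c (Os12g0568200) and OsUCL35 (Os11g0428800) were at 0.21 ± 0.21 against 60.2 ± 1.54 and 0.757 ± 0.159 against 61.3 ± 3.55 FPKM. AP2/ERF and DREB factors were higher in 12 and lower in 39 of 51 (camera adjusted p = 0.229). ERF102 was at 21.1 ± 1.45 against 421 ± 2.8 FPKM, 19.1-fold, DERF3 at 7.61 ± 1.11 against 164 ± 2.3 FPKM, 19.3-fold, and OsERF#133 at 0.187 ± 0.162 against 28.8 ± 2.43 FPKM. OsWRKY24 was at 61.4 ± 1.8 against 625 ± 11.1 FPKM. NAC factors were higher in 5 and lower in 31 of 36 (camera adjusted p = 0.0684). ONAC016 (Os01g0104200) was at 4.36 ± 0.361 against 49.2 ± 1.73, ONAC012 at 12.5 ± 1.28 against 119.6 ± 3.59 and NAC17 (Os11g0154500) at 2.28 ± 0.425 against 20.1 ± 1.48 FPKM.

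Class III peroxidases were higher in QJ in 14 and lower in 21 of 35. Their median was -0.80 and their mean 0.28 (camera adjusted p = 0.416). The peroxidases POX22.3 (Os07g0677200), POX8.1 (Os07g0677100) and prx29 were higher in QJ, at 678 ± 7.52 against 23.5 ± 2.81, 49.7 ± 0.442 against 1.58 ± 0.665 and 48.1 ± 2.64 against 0.77 ± 0.070 FPKM. Cell wall expansion and cellulose genes were higher in 9 and lower in 25 of 34 (camera adjusted p = 0.462). OsXTH11 was at 5.89 ± 1.2 against 137 ± 3.97, OsXTH9 (Os04g0604300) at 14.3 ± 0.67 against 129.6 ± 4.08 and OsXTH21 (Os07g0480800) at 8.87 ± 0.578 against 0.36 ± 0.052 FPKM. In phenylpropanoid, lignin and flavonoid synthesis 6 were higher and 24 lower of 30 (camera adjusted p = 0.164). The laccases OsLAC29, OsLAC28 and OsLAC10 (Os02g0749700) were at 18.4 ± 1.24 against 467 ± 3.61, 7.49 ± 0.229 against 99.5 ± 1.61 and 0.487 ± 0.0208 against 21.2 ± 0.854 FPKM. Heat shock factors and proteins were higher in 6 and lower in 23 of 29 (camera adjusted p = 0.308). The 3 named members, OsDjC29 (Os03g0323600), HSP18.8 (Os07g0517100) and OsHSP70 (Os01g0721000), were higher in QJ, at 19.6 ± 1.03 against 2.08 ± 1.54, 46.5 ± 3.25 against 6.16 ± 1.34 and 10.3 ± 1.63 against 2.2 ± 1.22 FPKM. Pathogenesis-related genes were higher in 4 and lower in 25 of 29 (camera adjusted p = 0.058), with OsPR5 at 21.4 ± 0.943 against 289 ± 2.07 FPKM. Limma with Benjamini-Hochberg adjustment passed 5629 of 5662 tested genes, 1924 higher and 3705 lower in QJ. The adjusted p of the 32 genes named by rule was at most 0.000125. Neither of the 2 list calls held with an estimated correlation.

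The fifth comparison tested whether the 2 varieties responded differently, as the stress change in QJ minus that in LJ. A difference above 0 is called toward QJ and one below 0 toward LJ. OsRMC went from 75.3 ± 1.04 to 318 ± 10.6 in QJ and from 14.5 ± 2.03 to 5058 ± 92.2 in LJ FPKM, a difference of -6.30 on the log2 scale, SE 0.0998. CAB1R fell in both, from 712 ± 6.9 to 213 ± 10.9 in QJ and from 672 ± 16 to 78.1 ± 1.29 in LJ FPKM, by less in QJ (1.35 on the log2 scale, SE 0.0462). All 16 tested light harvesting and photosystem genes differed, 15 of them toward QJ (camera adjusted p = 0.000127, adjusted p = 0.112 with an estimated correlation). OsTPP1 fell further in QJ, from 253 ± 2.14 to 10.9 ± 1.08 in QJ and from 638 ± 1.38 to 242 ± 4.28 in LJ FPKM (-3.03 on the log2 scale, SE 0.0709). All 10 inflorescence markers tested differed toward QJ (camera adjusted p = 0.000312, adjusted p = 0.0358 with an estimated correlation). OsMADS7 and OsMADS24 (Os09g0507200) were listed at 0 in QJ controls and were at 38.5 ± 1.69 and 36.1 ± 2.0 FPKM in LJ controls. MFO1 (Os02g0682200), a floral MADS-box gene, was at 22.4 ± 1.91 FPKM in LJ controls, 1.2 ± 0.215 FPKM in stressed LJ and below 1 FPKM in QJ. MADS14 (Os03g0752800) was highest in LJ controls as well, from 41.1 ± 3.56 to 43 ± 1.89 in QJ and from 204 ± 6.17 to 154 ± 2.97 in LJ FPKM.

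**Figure D1:**
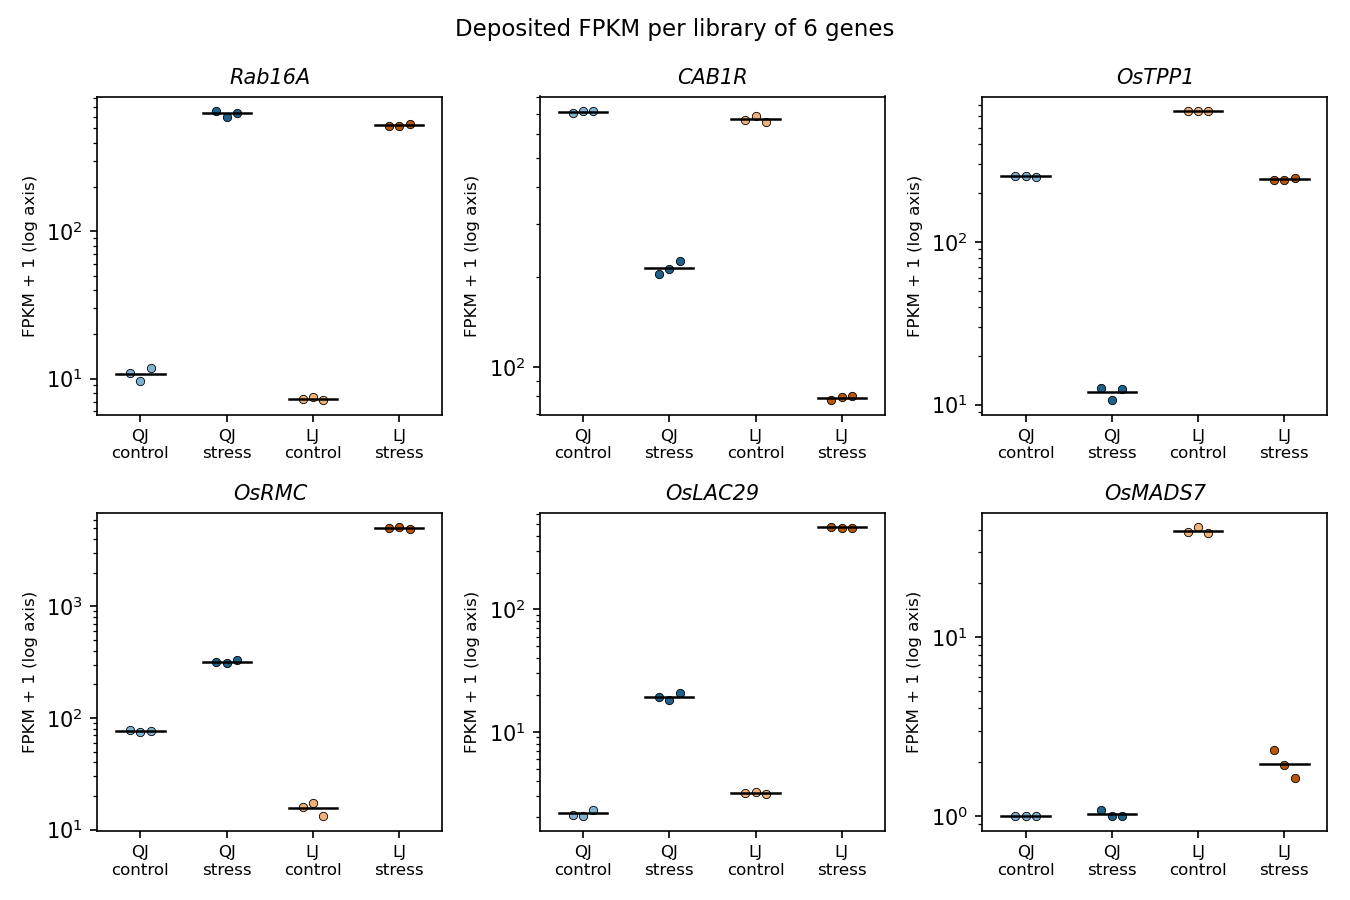
FPKM + 1 of 6 genes in each of the 12 libraries, on a log axis, with points for libraries and bars for the group means of 3 libraries. Rab16A rose in both varieties, OsRMC and OsLAC29 reached their highest values in stressed LJ, and OsMADS7 was high in the LJ controls.

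Among genes with the largest differences toward QJ, 5 were highest in the LJ controls and below 5 FPKM in the other groups. OSC6 was at 154 ± 3.35 FPKM there and at 0.597 ± 0.254 FPKM in stressed LJ, and Pox1(Px (Os05g0499300) at 68.1 ± 3.73 and 0.58 ± 0.0693 FPKM. Osc4 (Os08g0546300) was at 95.5 ± 1.44 and 4.48 ± 1.16, prx39 at 52.8 ± 0.828 and 0.723 ± 0.239, and OsFLA9 at 67.4 ± 1.59 and 0.81 ± 0.132 FPKM. Toward LJ, Sci1 rose from 33 ± 3.97 to 65 ± 5.51 in QJ and from 14.1 ± 2.64 to 1815 ± 16.7 in LJ FPKM and Cht2* from 4.25 ± 0.384 to 14.2 ± 1.16 in QJ and from 1.26 ± 0.126 to 227 ± 2.55 in LJ FPKM. The cation/proton exchanger OsCHX15 (Os12g0616500) reached 94 ± 2.83 FPKM in stressed LJ and 2.92 ± 0.0964 FPKM in stressed QJ. OsUCL35 was listed at 0 in both control groups and was at 0.757 ± 0.159 FPKM in stressed QJ and 61.3 ± 3.55 in stressed LJ. OsOxO3 was listed at 0 in QJ controls and was at 3.79 ± 0.469 FPKM in stressed QJ, and it went from 2.55 ± 0.294 to 414 ± 5.74 FPKM in LJ.

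Of 9 genes of proline, trehalose and raffinose metabolism, 4 differed toward QJ and 5 toward LJ (camera adjusted p = 0.504). OsTPP7 (Os09g0369400) fell from 285 ± 7.82 to 21 ± 1.2 in QJ and from 715 ± 8.29 to 231 ± 1.68 in LJ FPKM. OsTPP9 (Os03g0386500) rose from 2.04 ± 0.206 to 16.3 ± 0.33 in QJ and from 6.28 ± 0.595 to 11.9 ± 0.722 in LJ FPKM. Bicarbonate and organic acid genes differed toward QJ in 7 and toward LJ in 1 of 8 (camera adjusted p = 0.203). The carbonic anhydrase OsalphaCA2 (Os04g0412500) went from 9.38 ± 0.638 to 3.51 ± 0.275 in QJ and from 12.7 ± 1.09 to 1.13 ± 0.462 in LJ FPKM. OsALMT1 (Os04g0417000), of the malate transporter family, reached 2.53 ± 0.637 FPKM in stressed QJ and 9.63 ± 0.344 in stressed LJ, and the cytosolic malic enzyme OscytME3 (Os01g0743500) reached 8.63 ± 0.275 and 2.38 ± 0.13 FPKM. Of 4 chlorophyll synthesis genes, 3 differed toward QJ and 1 toward LJ. FGL (Os10g0496900), a protochlorophyllide oxidoreductase, went from 44.4 ± 3.14 to 24.2 ± 0.557 in QJ and from 67.6 ± 1.87 to 16.4 ± 1.51 in LJ FPKM. The magnesium chelatase subunit gene OsChlH (Os03g0323200) went from 73.4 ± 2.82 to 39.1 ± 1.17 in QJ and from 104 ± 0.555 to 32.1 ± 2.92 in LJ FPKM. OsPorA (Os04g0678700) went from 21.5 ± 1.1 to 5.12 ± 0.55 in QJ and from 31.5 ± 1.53 to 13.5 ± 0.58 in LJ FPKM. The photosystem gene PsbX (Os03g0343900) fell from 423 ± 16.8 to 187 ± 9.7 in QJ and from 420.0 ± 7.78 to 70.8 ± 2.19 in LJ FPKM. The chlorophyll a/b-binding gene CAB2R (Os01g0600900) fell from 507 ± 3.38 to 181 ± 2.56 in QJ and from 1166 ± 19.4 to 163 ± 4.68 in LJ FPKM.

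The 3 clock genes tested all passed. LHY (Os04g0583900) rose from 5.06 ± 0.306 to 31.3 ± 1.04 in QJ and from 1.31 ± 0.0702 to 30.6 ± 1.89 in LJ FPKM. ELF4_chr.11 (Os11g0621500) went from 33.1 ± 2.3 to 38.6 ± 0.575 in QJ and from 6.67 ± 1.35 to 5.85 ± 0.249 in LJ FPKM. OsPCL1 (Os01g0971800) went from 73.2 ± 0.73 to 94.8 ± 3.53 in QJ and from 21.4 ± 1.01 to 24.1 ± 1.61 in LJ FPKM. The small difference of ELF4_chr.11 (0.37 on the log2 scale) did not pass under the 3 other scalings, nor without 1 of 7 libraries (0.33 to 0.38). That of OsPCL1 (0.21) turned to -0.092 with median centring and -0.074 with the scaling of the authors' fold changes, and did not pass without 1 of 5 libraries (0.16 to 0.20). The list's median changed sign with scaling too. The reference genes tested were tubulins, and all 3 differed toward QJ. OsTUB1 (Os01g0282800) went from 2.71 ± 0.433 to 2.29 ± 0.455 in QJ and from 58.3 ± 1.7 to 4.9 ± 0.565 in LJ FPKM. OsTUB4 (Os01g0805900) went from 7.22 ± 1.06 to 5.39 ± 0.716 in QJ and from 84.6 ± 1.83 to 12.2 ± 0.476 in LJ FPKM. TUB8 (Os03g0661300) went from 3.27 ± 0.57 to 1.35 ± 0.108 in QJ and from 12.8 ± 0.264 to 3.12 ± 0.30 in LJ FPKM. Phenylpropanoid, lignin and flavonoid genes differed toward QJ in 20 and toward LJ in 9 of 31, and 2 did not pass (camera adjusted p = 0.504). OsLAC29 rose from 1.15 ± 0.131 to 18.4 ± 1.24 in QJ and from 2.18 ± 0.0451 to 467 ± 3.61 in LJ FPKM. OsLAC28 reached 7.49 ± 0.229 and 99.5 ± 1.61 FPKM and OsLAC10 0.487 ± 0.0208 and 21.2 ± 0.854 FPKM under stress in QJ and LJ.

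Among the fixed stress genes, NHX1 rose more in LJ (-0.999 on the log2 scale, SE 0.101), as did SGR (-1.13 on the log2 scale, SE 0.0472). The difference of NHX1 did not reach the threshold of 1 on the log2 scale. Rab16A differed slightly toward LJ (-0.29 on the log2 scale, SE 0.0893, adjusted p = 0.0123). That call ended with a pseudocount of 5 (-0.12) and with quantile normalization (-0.22). SKC1 was at 2.04 ± 0.145 FPKM in LJ controls and below 1 FPKM in the other groups. OSNCED3 rose in both varieties and its difference did not pass (0.04 on the log2 scale, SE 0.0831, adjusted p = 0.705). It passed below 0 with a pseudocount of 5 (-0.57), median centring (-0.26) and the scaling of the authors' fold changes (-0.25). It passed above 0 with a pseudocount of 0.1 (0.34) and quantile normalization (0.27). SNAC1 lacked values in some of the 12 libraries, so its difference was not tested, and no gene matched SOS1, P5CS1 or NAP.

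Further lists that differed were the secondary wall markers, 19 of 22 toward QJ and 3 not passing (camera adjusted p = 0.000127, adjusted p = 0.0349 with an estimated correlation). Cell wall expansion and cellulose genes differed toward QJ in 31, toward LJ in 6 and did not pass in 10 of 47 (camera adjusted p = 0.00499, adjusted p = 0.0403 with an estimated correlation). Both moved alongside the inflorescence markers. WRKY factors differed toward LJ in 19, toward QJ in 8 and did not pass in 6 of 33 (camera adjusted p = 0.00124, adjusted p = 0.0424 with an estimated correlation). Chlorophyll breakdown and senescence genes differed toward LJ in 8, toward QJ in 1 and did not pass in 2 of 11 (camera adjusted p = 0.00288, adjusted p = 0.0424 with an estimated correlation). Pathogenesis-related genes differed toward LJ in 15, toward QJ in 10 and did not pass in 4 of 29 (camera adjusted p = 0.0172, adjusted p = 0.155 with an estimated correlation). Adjusted over the list alone, the counts of 7 lists differed from these, by at most 1 gene, and that of phenylpropanoid, lignin and flavonoid genes was 30 in place of 29. Limma with Benjamini-Hochberg adjustment passed 3431 of 5170 tested genes, 2140 toward QJ and 1291 toward LJ. The balance depended on scaling: 62.4% of passing genes were toward QJ as deposited, 43.5% with median centring (1405 and 1827 genes), 53.8% with quantile normalization (1792 and 1540) and 48.4% with the scaling of the authors' fold changes (1593 and 1696). The median log2 difference over all genes tested was 0.21, -0.09, 0.05 and -0.002 in these settings.

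Between the 2 stress comparisons, which share no library, 1958 genes were tested in both. Of these 1115 were called higher and 689 lower in both varieties, 44 were higher in QJ and lower in LJ, and 102 were lower in QJ and higher in LJ. In the authors' deposited tables the counts for the 2338 genes listed in both were 1291, 862, 68 and 117. No test of overlap was made, because both tables hold selected genes.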

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

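The tests of scaling and of uneven pickup of tissue below were chosen only after the result was seen. The results here are those for which the stress response differed between QJ and LJ by the interaction test. In total 3431 genes differed, and 1 of 100 splits of the 12 libraries, the real one, gave as many, the highest of the others giving 2747. The tested genes had been selected by the authors on the real groups, which favours the real split, so chance was not excluded for this count. The 7 lists that differed were not beyond other splits: 16 of 100 gave as many, the highest of the others giving 10, so chance was not excluded. Splits that exchange few libraries keep part of the real difference. Median log2 differences of the lists were 1.06 for light harvesting and photosystems, 2.37 for inflorescence markers, 1.71 for secondary wall markers, 0.89 for cell wall expansion and cellulose, -0.48 for WRKY factors, -0.64 for chlorophyll breakdown and senescence and -0.29 for pathogenesis-related genes. All 7 kept their sign under the 3 other scalings, but not their size. With median centring the medians were -0.59 for pathogenesis-related genes, -0.77 for WRKY factors and 0.60 for cell wall genes. With the scaling of the authors' fold changes they were -0.57, -0.76 and 0.74.

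Differences of single genes are on the log2(FPKM + 1) scale and are no bound where a group was listed at 0. Positive ones in genes highest in the LJ controls were OSC6 6.56, Pox1(Px 5.45, Osc4 5.33, prx39 4.91, OsFLA9 4.60, OsMADS24 4.53, OsMADS7 4.38, MFO1 3.39 and SKC1 1.13. The tubulin genes gave OsTUB1 3.16, OsTUB4 2.34 and TUB8 0.89. Light harvesting and chlorophyll synthesis genes gave PsbX 1.38, CAB1R 1.35, CAB2R 1.35, FGL 1.14, OsChlH 0.78 and OsPorA -0.71. Genes with a larger rise in LJ gave OsRMC -6.30, Sci1 -5.97, OsUCL35 -5.15, Cht2* -5.12, OsCHX15 -4.77, OsOxO3 -4.62, OsLAC29 -4.03, OsLAC28 -3.70 and OsLAC10 -3.34. The trehalose phosphatase genes gave OsTPP1 -3.03, OsTPP7 -2.08 and OsTPP9 1.68. Genes of organic acid and bicarbonate metabolism gave OsalphaCA2 1.5, OsALMT1 -1.40 and OscytME3 1.36. Clock genes gave LHY -1.36, ELF4_chr.11 0.37 and OsPCL1 0.21. The fixed stress genes gave NHX1 -0.999, Rab16A -0.29 and SGR -1.13.

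Inflorescence markers were mostly highest in the LJ controls, with LHS1 (Os03g0215400) at 75.5 FPKM, OsMADS7 at 38.5 FPKM and MADS14 at 204 FPKM. MADS14 was also at 154 FPKM in stressed LJ and at 41.1 FPKM in QJ controls. Scaling was argued against, since the median log2 difference of the list was -3.07 between controls and -2.46 with median centring, the scaling that moved it most. Uneven pickup among the 3 LJ control libraries was argued against too, since their mean deviations spanned 0.0586. That span covers the 12 markers tested for LJ stress, which the authors had selected with the same libraries, and this may favour a small span. Inflorescence tissue in the LJ control samples may be a source: 94.4% of a separate list of anther and floral genes, 17 of 18, had their highest mean there, EAT1 being the exception, and 15 of 16 without DL and SPW1, which are also inflorescence markers. Only 5 of the 18 had values in all 4 groups, 4 of them highest in LJ controls, and SPW1 alone had a QJ mean of at least 1 FPKM. Those without values in all 4 groups had none in stressed QJ and were listed only for comparisons that include the LJ controls. That selection favours an extreme mean in LJ controls, so they are weak evidence. Some of the 18 were under 1 FPKM even there, such as ABCG15 at 0.637 and OsbHLH142 at 0.283 FPKM. Genes that are not listed could not count against this source. A difference in developmental stage between the varieties or treatments was not tested and stays open.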

How the results depend on the processing

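The scaling of the authors' fold changes, the restriction to genes of both variety tables, the removal of marker-list genes and list medians under quantile normalization were chosen only after the data were seen. Of 3206 values of named genes under an alternative, 3173 kept their side of the threshold and were not counted as reversed. Another 2 newly passed, 26 no longer passed and 5 reversed. A change of sign counted as reversed only where the value passed in the main setting or under the alternative. Of 921 list values, 763 likewise kept their call, 122 newly passed, 36 no longer passed and 0 reversed. The 763 did not all keep their direction, since medians of some lists that passed in neither setting changed sign, as for ethylene genes in LJ. Gene counts of the 4 pair comparisons and the difference stayed within 1.5 times of the main count in the alternatives run, with 2 exceptions. A mean of at least 5 FPKM in at least 1 group left 3871 genes between controls, of 6088, because fewer genes were tested. The threshold of 1 on the log2 scale left 1524 of 3431 for the difference, and for the overlap 405 of 689 genes lower in both, 28 of 44 and 48 of 102 with opposite calls, a stricter rule by construction. Leaving out 1 library gave 3164 to 3325 genes in QJ stress, 5034 to 5446 in LJ stress, 4614 to 5583 between controls (2723 to 2728 of the 4191 lower in QJ without an LJ control library), 4934 to 5094 between stressed groups and 3103 to 3347 for the difference, where fewer genes passed the filter. With a replicate block the counts were 3628, 5973, 6092, 5638 and 3437, and the lists 10, 18, 4, 2 and 7.

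List calls were the less stable part. With an estimated correlation 0, 0, 0 and 0 lists passed in the 4 pair comparisons, of 9, 16, 4 and 2, and 5 of 7 for the difference. Fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes, gave 27, 33, 33, 29 and 27. Without marker-list genes, and so without those lists, 7, 15, 1, 2 and 5 lists passed in place of 9, 16, 4, 2 and 7. Phenylpropanoid genes in QJ stress and cell wall genes between controls lost their call, and replication genes in LJ stress gained one. In the full lists median centring gave 10, 16, 5, 4 and 8, and the scaling of the authors' fold changes 9, 17, 3, 2 and 8. With median centring sucrose and starch genes passed in QJ stress (0.0445), jasmonate genes between controls (0.0199), between stressed groups (0.0477) and for the difference (0.0297), and pathogenesis-related genes between stressed groups (0.0477). With the scaling of the authors' fold changes replication genes passed in LJ stress (0.0481) and jasmonate genes for the difference (0.0196), and cell wall genes no longer passed between controls (0.0529). The difference over genes listed in both variety tables passed in 2370 of 3596. For the difference without that restriction, the passing genes shared with the main setting were 2714 with median centring, 2992 with quantile normalization and 2900 with the scaling of the authors' fold changes. Median list values changed sign under another scaling for heat shock genes in QJ, ethylene genes in LJ, Calvin cycle and light harvesting genes between controls, iron genes between stressed groups and 7 lists for the difference, none of them a called list.

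Folds of genes low in 1 group shifted with the pseudocount. With 0.1 and 5 in place of 1 the log2 change was 8.86 and 6.85 for OsLEA3-1 in LJ (8.22) and 3.88 and 1.92 for OsLAC29 in QJ (3.17). Reversed differences were OsPCL1, -0.092 with median centring and -0.074 with the scaling of the authors' fold changes, and OSNCED3, -0.57 with a pseudocount of 5, -0.26 with median centring and -0.25 with that scaling. OSNCED3 passed at 0.34 with a pseudocount of 0.1 and 0.27 with quantile normalization. OsALMT1 was -0.89 and missed the threshold with a pseudocount of 0.1. ELF4_chr.11 missed it at 0.39 with a pseudocount of 0.1, 0.071 with median centring, 0.086 with quantile normalization and 0.11 with the scaling of the authors' fold changes. It also missed it without QJ_CK replicate 2 (0.36) or 3 (0.33), QJ_N replicate 1 (0.37), 2 (0.36) or 3 (0.38), or LJ_N replicate 2 (0.38) or 3 (0.34). OsPCL1 missed it without QJ_CK replicate 3 (0.20), QJ_N replicate 1 (0.18), LJ_CK replicate 1 (0.19) or 3 (0.19), or LJ_N replicate 1 (0.16). The cause was not tested. Count-based models were not run, because no counts were recovered from FPKM. Depth is unknown and limits genes of low FPKM most.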

Other observations

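The genes named next, the test of tissue loss, the test of genes lower in both conditions and the test of scaling between stressed groups were chosen only after the result was seen. Of the 102 genes that fell in QJ and rose in LJ, 44 have a name. They include the factor OsWRKY69 (Os08g0386200), from 548 ± 1.75 to 71.3 ± 4.42 in QJ and from 157 ± 4.71 to 356 ± 4.28 in LJ FPKM, with a difference of -4.10 on the log2 scale. OsWRKY70 went from 90.5 ± 2.08 to 23.3 ± 0.552 in QJ and from 115 ± 4.5 to 322 ± 7.51 in LJ. OsSDS1 (Os01g0864500) went from 811 ± 9.78 to 191 ± 7.18 in QJ and from 626 ± 15.5 to 1559 ± 14.4 in LJ FPKM. The ribonuclease gene RNS4 (Os09g0537700) went from 192 ± 3.68 to 78.1 ± 2.53 in QJ and from 17.5 ± 1.01 to 86 ± 3.54 in LJ FPKM. The calmodulin-like gene OsCML31 (Os01g0955100) went from 726 ± 14 to 185 ± 14.6 in QJ and from 486 ± 8.37 to 908 ± 12.2 in LJ FPKM. The asparagine synthetase gene ASN1 (Os03g0291500) went from 158 ± 0.667 to 85.7 ± 1.52 in QJ and from 42.1 ± 1.17 to 151 ± 2.39 in LJ FPKM, and the protein phosphatase gene OsPP2C32 (Os03g0292100) went from 448 ± 3.53 to 129 ± 2.04 in QJ and from 268 ± 3.18 to 514 ± 16.7 in LJ FPKM. Of the 44 genes that rose in QJ and fell in LJ, 19 have a name. The O-methyltransferase gene ROMT9 (Os08g0157500) went from 47.3 ± 1.26 to 198 ± 9.75 in QJ and from 205 ± 3.88 to 82.8 ± 1.08 in LJ FPKM. The defensin-like gene DEFL8 (Os03g0130300) went from 16.1 ± 1.61 to 42.9 ± 1.9 in QJ and from 132 ± 4.77 to 21.7 ± 5.13 in LJ FPKM.

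Further lists that passed camera in neither stress comparison, or had fewer than 5 tested members, had these counts. The tested members of a list could differ between QJ and LJ, since each comparison holds its own selected genes. The counts therefore do not compare the responses of the same genes. Common reference genes rose in 0 and fell in 1 of 1 in QJ, against 2 and 5 of 7 in LJ, with a median of -1.74 in LJ (camera adjusted p = 0.25). Those that fell in LJ were 4 tubulin genes and ACT2, and TubA and rubq2 rose. Between controls all 7 reference genes tested were lower in QJ, with a median of -2.02 (camera adjusted p = 0.115), and between stressed groups all 4, with a median of -0.90. Clock genes rose in 1 and fell in 1 of 2 in QJ, against 2 and 0 of 2 in LJ. Auxin genes rose in 5 and fell in 16 of 21 in QJ, against 10 and 21 of 32 in LJ, where 1 did not pass in LJ. Glutathione S-transferase genes rose in 6 and fell in 9 of 15 in QJ, against 11 and 19 of 30 in LJ. Aquaporin genes rose in 4 and fell in 1 of 5 in QJ, against 2 and 8 of 10 in LJ. Bicarbonate and organic acid genes rose in 6 and fell in 3 of 9 in QJ, against 9 and 5 of 14 in LJ. Sucrose, starch and sugar transport genes rose in 15 and fell in 4 of 19 in QJ, against 15 and 10 of 25 in LJ. Nitrogen genes rose in 5 and fell in 6 of 11 in QJ, against 12 and 8 of 20 in LJ, with a median of -0.87 and a mean of 0.39 in QJ. Proline, trehalose and raffinose genes rose in 7 and fell in 2 of 9 in QJ, against 8 and 3 of 11 in LJ. Antioxidant enzyme genes rose in 3 and fell in 1 of 4 in QJ, against 5 and 4 of 9 in LJ. Chlorophyll synthesis genes rose in 0 and fell in 4 of 4 in QJ, against 1 and 7 of 8 in LJ. Cytokinin and gibberellin genes rose in 5 and fell in 2 of 7 in QJ, against 7 and 7 of 14 in LJ. Replication and division genes rose in 2 and fell in 4 of 6 in QJ, against 2 and 12 of 14 in LJ. Organelle-encoded genes rose in 0 and fell in 8 of 8 in QJ, against 4 and 3 of 7 in LJ. The 8 in QJ hold fewer separate measurements, since gene-ndhB and gene-ndhB-2 had identical means and SDs, as had gene-rp12 and gene-rpl2. Ethylene genes rose in 1 and fell in 0 of 1 in QJ, against 4 and 4 of 8 in LJ, the LJ median turning from -0.12 to above 0 with the scaling of the authors' fold changes. Jasmonate genes rose in 11 and fell in 9 of 20 in QJ, against 7 and 4 of 11 in LJ, with a median of 0.72 and a mean of -0.11 in QJ. Heat shock genes rose in 9 and fell in 10 of 20 in QJ, against 10 and 13 of 23 in LJ, with 1 not passing and a median in QJ of -0.04 that was above 0 with quantile normalization. Root markers rose in 1 and fell in 0 of 1 in QJ, against 1 and 2 of 3 in LJ. In LJ 1 of 1 seed storage marker rose, and none was listed in QJ.

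Over the 3596 tested genes of both variety tables, chosen by the authors for differing between varieties in the same libraries and in part listed for stress too, the median size of the log2 response was 0.439 in QJ and 0.623 in LJ. The response was larger in LJ for 58.3% of them, 756 had a response of at least 1 in QJ and 1171 in LJ, and the correlation across genes was 0.533, genes not being independent replicates. With its sign kept, the median response was -0.0008 in QJ and -0.243 in LJ. The sizes were not computed under the other scalings, and a shift of all values of a group would change them. Any of these genes near 0 in QJ in both conditions could show a large response only in LJ, and such genes were not set apart.

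Of genes listed between controls 71.1% were lower in QJ, and 67.9% between stressed groups. Neither the authors' scaling nor median centring evened the split between controls. A log2 shift of 0.92 was needed, against a shift of 0.15 between the deposited values and the authors' fold changes in the controls. Median centring moved the median of the tested control genes from -1.02 to -0.41, by less than 0.92, and left 1910 genes higher and 3520 lower in QJ. These scalings do not bound how far off the libraries may be, so a larger scaling shift was not excluded. The threshold used for the shift of 0.92 was settled after values were seen, and a higher one gave 1.27. Between stressed groups scaling cannot be told apart, since a shift of 0.58 was needed against one of 0.354, more than that shift but less than 2 times it. The higher threshold gave 0.74, slightly more than 2 times it, so the outcome there rested on the threshold. Of the strongly lower genes 47.0% (1537 of 3269) were also listed as lower in QJ under stress. That is under the bound set for a sequence difference from the reference as the cause. A gene can be listed there as lower only if stressed LJ still expresses it, which OSC6 and OsLTP1.3, for example, hardly did. The share therefore does not decide on a sequence difference. For those 1537 genes a sequence difference cannot be told apart from lower expression, because the sequences of the varieties were not used here. The same holds for genes at or near 0 in LJ in both conditions, such as OsWAK123, Sc-j and FAAH. Between controls inflorescence tissue in the LJ samples cannot be told apart, since without the genes lower in LJ under stress 59.4% (3144 of 5295) were still lower in QJ, between the bounds set, and that removal used the same LJ control libraries. Inflorescence tissue in the stressed LJ samples was not separated by these tests and stays open. There all 6 inflorescence markers tested were lower in QJ than in LJ, with a median of -1.46 (camera adjusted p = 0.195). MADS14 was at 43 ± 1.89 against 154 ± 2.97 FPKM and LHS1 at 2.4 ± 0.265 against 9.92 ± 0.202 FPKM. A difference of variety stays open.

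More genes were listed for stress in LJ than in QJ, 7178 against 4324, a ratio of 1.66, with 1.78 for genes that fell. For loss of inflorescence tissue from LJ samples, the ratio for genes that rose was 1.55, above the bound set for that cause. FPKM are scaled to library size, so loss of a tissue would also raise the values of genes of the remaining tissue. The ratio therefore cannot decide, and loss of inflorescence tissue stays open. Lower noise or greater depth was argued against, since among abundant genes with large changes, where noise does not limit a call, the ratio was 1.68 (1115 against 662). A difference between the varieties in their response, in the timing of sampling or in dose reached in the leaf was not separated by these tests and stays open.

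For the pair comparisons 10 splits of 6 libraries are possible, too few for a share under 0.05, and the genes had been selected on the real groups. For gene counts 1 of 10 splits gave as many calls in each of the 4, the real one, with 3629, 5970, 6088 and 5629 genes against 0 in the highest other. For called lists, 10 of 10 splits gave as many in QJ stress (9 against 12 in the highest other), 1 in LJ stress (16 against 15), 10 between controls (4 against 5) and 6 between stressed groups (2 against 2).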
